A study of Mus musculus with 9 samples.

How the data were processed

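Blood cells of 4 healthy and 5 arthritic female 129SvE mice were profiled by Seq-Well. Per the labels, read 1 carried the barcode, read 2 started from the polyA tail, and reads were processed with the Drop-seq core computational protocol on build GRCm38.p5. The aligner and its version, the cell filter and the method of calling cell types are not given in the sources used here. The deposited values are signal: whole-number sums per gene and barcode, not scaled to a common total, in which a column appears to hold several similar cells, so they are not treated as counts of single cells. This reading rests on the values themselves, since 1313 of 4310 columns were identical to another and close columns lay nearer than counting noise allows. A second deposited table of joint data, with 8423 columns, was not used, because its columns match none of the blood samples.

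The table held 23499 genes, with 6052 to 51601 signal and 1764 to 8250 genes per column. All 4310 columns passed the filter of at least 200 genes and under 20% mitochondrial signal, so no setting of this filter that was foreseen changes anything. The 9 deposited cell classes were used in place of a new clustering; 3 of them, with 8 columns together, were too small to compare. Hemoglobin share covers 10 genes and mitochondrial share 26.

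Signal was summed over the columns of each mouse, scaled with TMM factors (trims of 30% and 5%), expressed per 1000000 (signal per 1000000, SPM) and taken as log2 with a pseudocount of 1. Genes at 10 SPM or more in at least as many mice as the smaller group holds were tested with limma 3.58.1 (trend, no weights, R 4.3.3), with a Benjamini-Hochberg adjusted p under 0.05 as the threshold. A count test had been planned, but the values did not behave as counts of separate cells, and this replaced it. Mice are the replicates; columns identical between mice make them less independent than the tests assume. A class was to enter with 20 columns per mouse, but no class had 3 healthy mice at that minimum. A minimum of 5, chosen after the data were seen, left granulocytes (4 and 5 mice) and B cells (3 and 5 mice). Lists with at least 5 tested members, of 32 fixed lists, were tested with camera (preset correlation 0.01), with camera on an estimated correlation and fry beside it. Shares and measures per mouse were compared with two-sided exact permutation tests over 126 splits, where the smallest possible p is 0.0159. The difference between classes was fitted with limma, without the trend, on the difference of each mouse's class values.

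The comparisons, lists, markers, the rule for named genes and most alternatives were fixed before the data were examined. Over all cells the rule names up to 10 genes per direction with the largest change among those past the threshold with a mean of at least 20 SPM, leaving out unnamed gene models, and 5 per direction in each class. Where none passes, it names the 5 smallest p per direction. It adds up to 4 members of each list with the smallest p over all cells, and 3 genes for the difference between classes. The text gives part of the genes that the rule names. A further 2 are not reported here, and no others took their place. Coordinates are from GENCODE M21.

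The fit was tested on simulated data with the group sizes, total signal and spread per gene of these mice. Genes and mice were drawn independently there, with the same spread in both groups and no columns shared between mice. The fit recovered 34.3%, 79.1% and 93.9% of genes changed by 1, 2 and 4 on the log2 scale over all cells. In granulocytes it recovered 11.9%, 40.3% and 77.3%, and in B cells 2.99%, 17.9% and 65.2%. False calls numbered 6, 5 and 5, and where no gene changed it called 0 in each. These numbers do not measure error in the real mice, where other splits of the mice called up to 175, 22 and 128 genes. Total signal per mouse was 335933, 2053973, 330950 and 560605 in healthy mice 1 to 4. It was 13557201, 12313036, 9019004, 9024928 and 8350920 in arthritic mice 1, 3, 4, 5 and 6. Because columns overlap in content, no counting intervals are given.

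Alternatives changed the scaling, the filter, the pseudocount, the weights, the columns, the genes or the mice used, covariates, and thinned each mouse to the smallest total. Settings foreseen but not run are a Wald test for counts, doublet removal, other clustering resolutions, thinning before clustering and a leukocyte-only denominator, since they need counts or a new clustering. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 did the remaining work.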

Results

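Blood was collected from 9 female mice of the 129SvE strain, 4 healthy and 5 with experimental arthritis, an animal model of rheumatoid arthritis in which the joints become inflamed. Peripheral blood cells were read out by Seq-Well, a method that captures single cells with barcoded beads in an array of small wells. The deposited table held 4310 barcode columns and 23499 genes, and every column carried the mouse it came from and the name of a cell class. Healthy mice 1, 2, 3 and 4 gave 30, 201, 26 and 45 columns, and arthritic mice 1, 3, 4, 5 and 6 gave 1027, 964, 721, 502 and 794. The mean was 75.5 ± 84.1 columns per healthy mouse and 802 ± 208 per arthritic mouse (SD, n = 4 and 5; two-sided exact permutation p = 0.0159, the smallest p this design allows, adjusted p = 0.037 over 7 measures). Total signal lay between 330950 and 2053973 in the healthy mice and between 8350920 and 13557201 in the arthritic mice, so over all cells the values of healthy mice rest on less material.

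Hemoglobin transcripts, which come from red cells and their precursors, made up 17.2%, 1.68%, 55.0% and 41.5% of the signal of healthy mice 1 to 4. In arthritic mice 1, 3, 4, 5 and 6 they made up 0.772%, 0.630%, 33.8%, 50.0% and 3.61% (two-sided exact permutation p = 0.429, n = 4 and 5). Mitochondrially encoded transcripts took 8.74% ± 2.97 in the healthy and 5.71% ± 2.35 in the arthritic mice (SD; exact permutation p = 0.159). The columns were not independent profiles. Of the 4310, 1313 were identical to another column in every gene, and 59 of the 302 healthy columns (19.5%) were identical to a column of an arthritic mouse. The mice therefore share part of their values, and the p-values below, which treat mice as independent, are to be read with that in mind.

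The first comparison asked whether the makeup of the blood differed between healthy and arthritic mice. Granulocyte columns, whose leading genes were the neutrophil transcripts Ltf, S100a9, Cd177, Camp and Ngp, took 33.1% ± 20.5 of a healthy mouse's columns and 49.8% ± 22.2 of an arthritic mouse's (SD, n = 4 and 5; two-sided exact permutation p = 0.397). Leading genes of each class were taken over the columns of all mice together. Healthy mice gave 5 to 20 granulocyte columns each and arthritic mice 249 to 489, so these genes describe mainly the arthritic columns. The class deposited as B cells took 30.6% ± 21.1 and 26.1% ± 19.5 (exact permutation p = 0.730). Its leading genes included Igkc but also Ighg1, Jchain and Iglv1, transcripts of antibody-secreting plasma cells, so the class covered both. The class deposited as CD4 T cells, led by AF357399, Cd3e and Themis among others, took 11.5% ± 18.8 and 8.24% ± 5.36 (exact permutation p = 0.825). All 18 T cell markers were highest in this class among the 6. Over the columns of all mice it held Cd8a, a marker of CD8 T cells, at 84.1 SPM beside Cd4 at 119 SPM. Its share is therefore not one of CD4 T cells alone, and the name is used below as a label only. Common myeloid progenitors took 0.680% ± 1.05 and 4.64% ± 3.15, with an exact permutation p of 0.0476 that became 0.286 after adjustment over the 6 classes. Their leading genes were Car1, Nfia, Pklr and Mt2, and Car1 is a carbonic anhydrase of red cell precursors. Myeloid dendritic cells took 4.01% ± 6.29 and 2.81% ± 2.20 (exact permutation p = 0.841). Among the 6 classes, 9 of 11 dendritic markers and 15 of 21 monocyte markers were highest in this one, so it covered both.

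The class named after foxP3 T cells took 20.1% ± 23.5 of the columns of healthy mice and 8.17% ± 11.3 in arthritic mice (SD, n = 4 and 5; exact permutation p = 0.413). Its median hemoglobin share was 37.6%, and Foxp3, the transcription factor that defines regulatory T cells, reached 2.2 SPM (signal per 1000000) in it against 15 SPM in the CD4 T class. Il4, Klra4, Gzma, Ccl5, Bpgm and Alas2 were among its 10 leading genes. Of its 331 columns, 203 came from arthritic mouse 4, so these pooled values describe mainly that mouse. By mouse, hemoglobin took from 0.174% of the class's signal in arthritic mouse 1 to 61.9% in arthritic mouse 5. Among the 6 classes, 12 of 16 NK markers, 8 of 16 erythroid markers and 0 of 18 T cell markers were highest in this one. No class share passed the adjusted threshold, and healthy mouse 2 lay apart from the other healthy mice in 2 of the 6 classes, granulocytes and CD4 T cells. Without that mouse the granulocyte difference changed from 16.7 to 6.45 percentage points (7.46 without arthritic mouse 5), the B-cell difference from -4.46 to 3.75 (1.63 without arthritic mouse 5) and the CD4 T difference from -3.25 to 6.02; without healthy mouse 3 the foxP3 difference changed from -11.9 to -0.644, and without healthy mouse 1 the dendritic cell difference changed from -1.21 to 1.90.

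**Figure D1:**
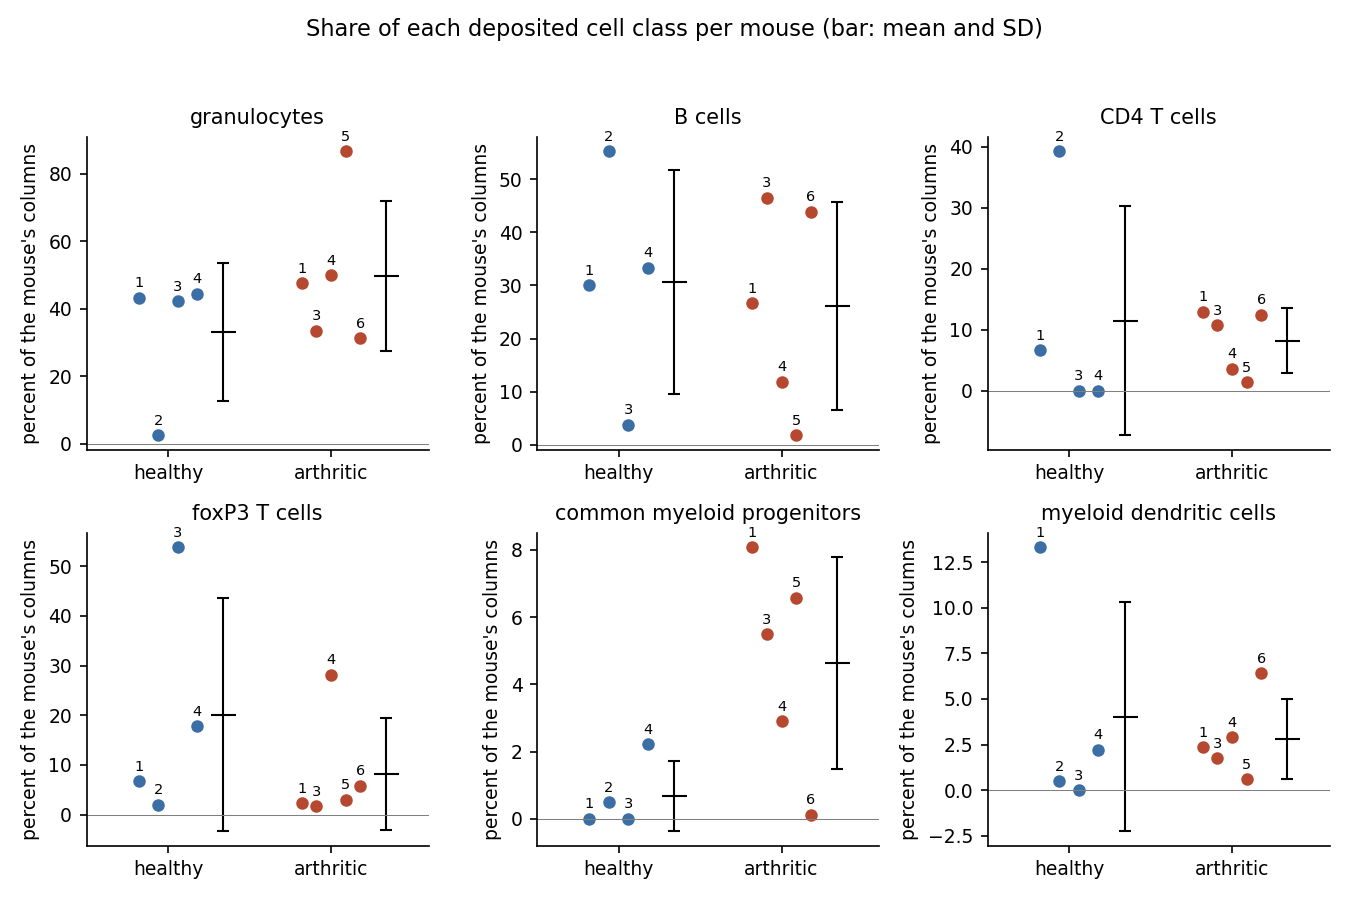
Share of each deposited cell class (percent of the mouse's columns, vertical axis) in healthy and arthritic mice; each point is a mouse with its number, and the bar gives the mean and SD. Healthy mouse 2 lies apart with 2.49% granulocytes and 39.3% CD4 T cells, and the groups overlap in each of the 6 panels.

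The second comparison asked which transcripts differed between arthritic and healthy blood over all cells of each mouse. Cd177, a surface protein of neutrophils, rose from 11.5 ± 5.46 to 203 ± 110 SPM (SD, n = 4 and 5), a log2 difference of 3.85 ± 0.55 (SE; limma adjusted p = 0.0428). A set of 3 small noncoding transcripts went the other way and lay lower in 5 of 5 arthritic mice than in every healthy mouse. Mir6236 fell from 7361 ± 1351 to 1629 ± 431 SPM (log2 difference -2.20 ± 0.26, adjusted p = 0.0227) and Mir6240 from 128 ± 6.21 to 32.9 ± 10.5 (-1.99 ± 0.25, adjusted p = 0.025). AF357399, a small nucleolar RNA, fell from 334 ± 90.6 to 72.4 ± 28.9 SPM (-2.25 ± 0.32, adjusted p = 0.0428). These 4 were all that limma called among 8459 genes tested, while 1133 had an unadjusted p under 0.05. Log2 values are on the scale of SPM plus 1, which understates the change of low genes. Unscaled means, an alternative, are on the scale of mean signal per column plus 1, which understates it further. They gave the difference nearest to no change for each of these 4 genes. Over the alternatives and single mice left out the log2 difference ran from 1.604 to 4.33 for Cd177, -2.46 to -1.91 for Mir6236, -2.35 to -0.77 for Mir6240 and -2.49 to -1.28 for AF357399, without a change of sign.

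On the GRCm38 assembly with GENCODE M21 annotation, Cd177 is a protein-coding gene on the minus strand of chromosome 7, from 24743983 to 24760311. Mir6236 is annotated as a microRNA gene on chromosome 9, from 110281287 to 110281409, and Mir6240 as one on chromosome 5, from 114851948 to 114852064. AF357399 lies on chromosome 7, from 28351508 to 28351632. The assay primes on polyA tails, and the values count signal assigned to these intervals, not mature small RNAs. The median log2 difference of all genes was 0.257 with the scaling used, 0.152 with median-of-ratios factors, 0.314 with scaling by the total alone and 0.105 for unscaled means. Relative to the median of all genes, Cd177 stood at 3.59, Mir6236 at -2.45, Mir6240 at -2.25 and AF357399 at -2.51.

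Genes of neutrophil granules were higher as a group in arthritic mice over all cells. All 28 tested members of the list of S100 alarmins and granule proteins had higher means in arthritic mice, with a median log2 difference of 2.04 (1.79 above the median of all genes). Cd177 alone passed over all genes, and 22 members passed when adjusted over the list alone. The iron-binding protein Ltf stood at 112 ± 50.4 and 1846 ± 1050 SPM (log2 difference 3.77 ± 0.61, adjusted p = 0.0616), and Lcn2, which binds bacterial siderophores, at 56.1 ± 23.4 and 788 ± 445 (3.53 ± 0.61, adjusted p = 0.0791). The gelatinase Mmp9 had a log2 difference of 2.31 ± 0.42 (adjusted p = 0.0861). Each of these was higher in 5 of 5 arthritic mice than in every healthy mouse. The set test camera placed the list above other genes (adjusted p = 4.3e-19 with its preset correlation of 0.01; adjusted p = 0.358 with an estimated correlation). The overlapping list of neutrophil markers had a median of 2.31, with 0 of 21 members past limma's threshold over all genes and 14 adjusted over the list alone; G0s2 in it had a log2 difference of 3.08 ± 0.47 (adjusted p = 0.0604). Its camera adjusted p was 8.4e-13, and 0.358 with an estimated correlation. For unscaled means per column the medians were 1.14 for the alarmin and granule list and 0.79 for the neutrophil markers, against 2.04 and 2.31. There the pseudocount weighs more and the median of all genes was 0.105.

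Camera placed 3 further lists above other genes. Nuclear genes of oxidative phosphorylation had a median log2 difference of 0.35 (35 of 37 positive; adjusted p = 3.9e-04, and 0.576 with an estimated correlation), Atp5j at 0.59 ± 0.21 and Uqcrq at 0.71 ± 0.27 among them. Glycolysis and hypoxia genes had a median of 0.67 (adjusted p = 0.0144, and 0.468 with an estimated correlation), with 4 of 14 past the threshold adjusted over the list alone; the hexokinase Hk2 stood at 8.37 ± 5.48 and 33.3 ± 7.77 SPM (2.00 ± 0.38). Proliferation genes had a median of 0.75, and 20 of 20 were positive (adjusted p = 0.0214, and 0.780 with an estimated correlation). Outside the rule for named genes and chosen after its values were seen, Gm42418, an unnamed lincRNA on chromosome 17 whose interval lies within that of the rRNA gene CT010467.1 on the other strand, took 5.37% ± 1.76 of the signal of healthy mice and 1.80% ± 0.671 of that of arthritic mice (SD, n = 4 and 5; exact permutation p = 0.0159, adjusted p = 0.037 over 7 measures).

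Camera placed 12 lists below other genes, and lymphocyte genes made up much of them. Mitochondrially encoded transcripts had the smallest p among them, with a median log2 difference of -0.48 and 0 of 9 positive (camera adjusted p = 3.6e-08, and 0.358 with an estimated correlation); mt-Rnr1, the small mitochondrial ribosomal RNA, stood at 16704 ± 4033 and 9153 ± 2271 SPM. T cell receptor signalling had a median of -0.36 (adjusted p = 1.1e-05, and 0.548) and T cell markers one of -0.39 (adjusted p = 2.8e-05, and 0.576), with Il7r at -0.82 ± 0.39 and Lef1 at -0.55 ± 0.33. Markers of NK cells had a median of -0.79, Klrk1 at -1.25 ± 0.36, and B cell receptor signalling a median of -0.26, Ighd at -0.87 ± 0.34. The remaining lists on this side were lymphocyte quiescence and homing, interferon-gamma GTPases, B cell markers, erythroid transcripts, MHC class II presentation, cytotoxic effector genes and the glucocorticoid response. With an estimated correlation the adjusted p of the lists on this side lay between 0.358 and 0.746, so none was called. Medians of 5 of the 12 changed sign for unscaled means per column before the shift of all genes was taken off, and none did so after.

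Lists of other inflammatory pathways were not called by camera over all cells. Of the type I interferon response, 22 of 29 members were positive with a median of 0.30 (adjusted p = 0.277), and Rtp4, Ifit1 and Oas1a stood at 1.36 ± 0.35, 1.29 ± 0.38 and 1.59 ± 0.47. The TNF and NF-kB list had a median of 0.39 (adjusted p = 0.683), with Nfkbiz at 1.17 ± 0.28 and Cxcl2, a neutrophil-attracting chemokine, at 1.80 ± 0.45; 3 of its 28 members passed when adjusted over the list alone. The monocyte markers Ly6c2 and Lyz2 stood at 1.25 ± 0.36 and 1.42 ± 0.56, Ear2 at 0.83 and Ms4a6b at -0.64. Their list had a median of 0.16 with 10 of 18 positive, and camera's direction for it was downward (adjusted p = 0.294). Among the 6 classes Ly6c2 and Lyz2 were highest in granulocytes, at 521 and 11356 SPM. An exact permutation test of each mouse's mean over a list gave 7 lists with an unadjusted p under 0.05 and 0 after adjustment, where the smallest p it can give is 0.0159; camera with an estimated correlation and fry also called 0.

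The calls over all cells depended on single mice. Without healthy mouse 1, 2 or 4, or arthritic mouse 1 or 3, limma called 0 genes; without healthy mouse 3 or arthritic mouse 4 it called 1, without arthritic mouse 5 it called 3 and without arthritic mouse 6 it called 64. With limma's weights for each mouse, without a filter on low genes, or without arthritic mice 1 and 3, whose hemoglobin shares were lowest, it called 0.

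**Figure D2:**
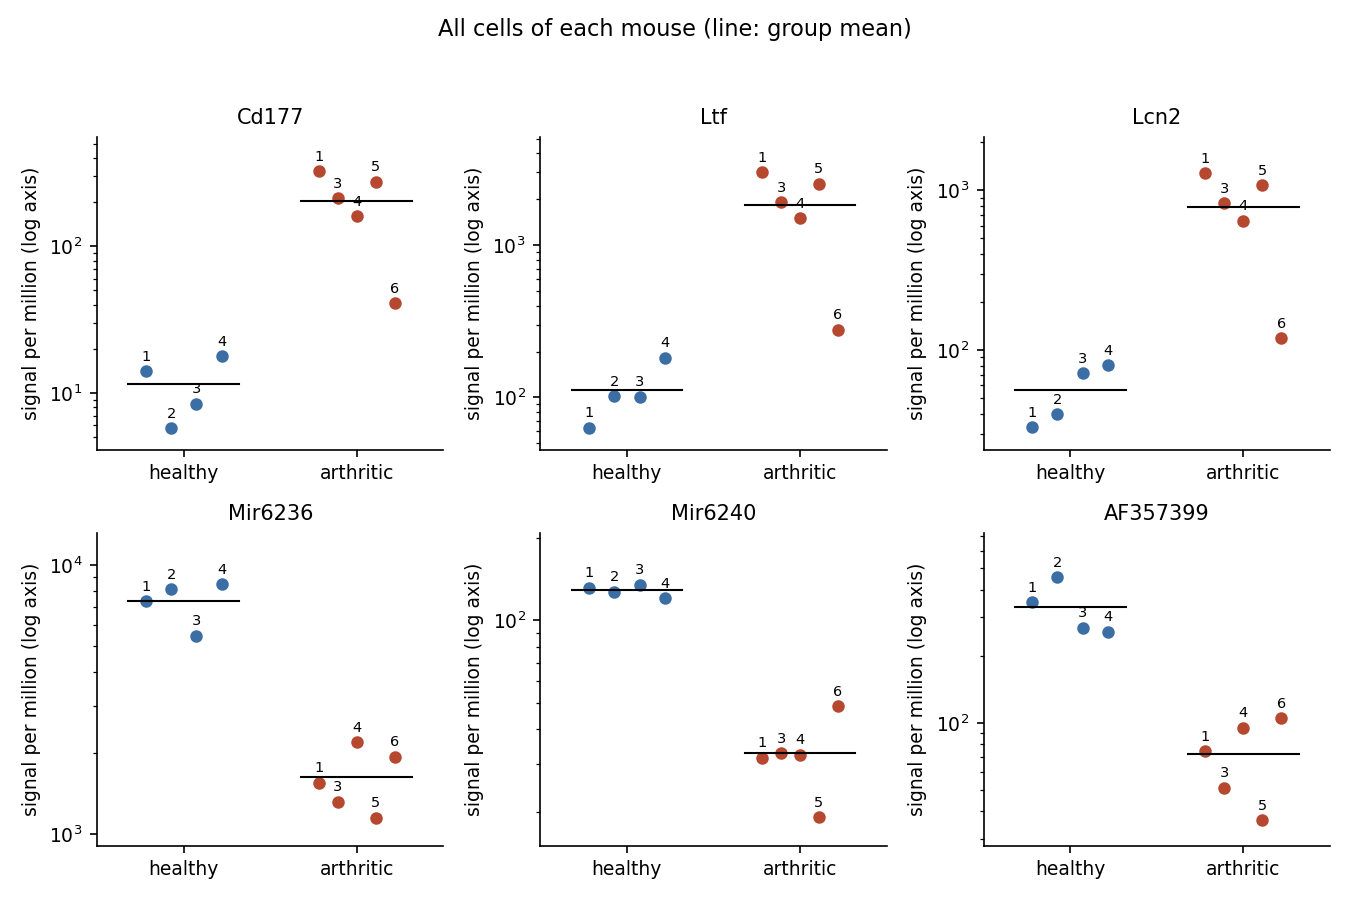
Signal (SPM) (vertical log axis) over all cells of each mouse for 6 transcripts; each point is a mouse with its number and the line is the group mean. Cd177 lay at 5.77 to 17.8 SPM in healthy mice and at 40.9 to 325 in arthritic mice, and Mir6240 at 120 to 135 against 19.1 to 48.6.

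The third comparison asked for the same differences within granulocytes, in 4 healthy mice with 5 to 20 columns and 5 arthritic mice with 249 to 489. Limma called 52 of 7935 genes, 46 higher and 6 lower in arthritic mice, and 1712 had an unadjusted p under 0.05. Of the 52 it called 5 with median-of-ratios factors and 2 with scaling by the total alone. With median signal per column as a covariate it called 1 of them, and with hemoglobin share 8. Cd177 rose from 45.2 ± 51.9 to 440.1 ± 298 SPM (log2 difference 3.58 ± 0.70, adjusted p = 0.046) and Lrg1, a secreted glycoprotein stored in neutrophil granules, from 47.2 ± 42.6 to 411 ± 235 (3.27 ± 0.53, adjusted p = 0.0341). Retnlg, a resistin-like protein of neutrophils, rose from 499 ± 248 to 2289 ± 818 SPM (2.23 ± 0.35, adjusted p = 0.0298). Dfna5, which encodes the pore-forming gasdermin E, rose by 2.25 ± 0.39 and Abhd2, an alpha/beta hydrolase, by 2.15 ± 0.39 on the log2 scale. Both rested on unscaled signal sums of 1, 1, 1 and 2 in healthy mice 1 to 4 (Cd177 on 4, 10, 1 and 7, Lrg1 on 3, 9, 3 and 9), and over the alternatives and single mice left out the log2 differences ran from 0.51 to 3.27 for Dfna5, 0.47 to 3.50 for Abhd2, 1.94 to 4.99 for Cd177, 1.90 to 4.38 for Lrg1 and 2.05 to 2.73 for Retnlg. The lowest value of each range came from unscaled means per column, where the pseudocount weighs more. Each of these 5 genes was higher in 5 of 5 arthritic mice than in every healthy mouse.

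Lower in the granulocyte columns of arthritic mice were Col1a2, a chain of type I collagen, at 147 ± 64.6 and 13.9 ± 5.81 SPM (log2 difference -3.30 ± 0.38, adjusted p = 0.0132), and the muscle protein titin, Ttn, at 57.5 ± 22.5 and 9.83 ± 7.60 (-2.55 ± 0.50, adjusted p = 0.0491). Mir6236 fell from 8657 ± 3539 to 1297 ± 488 SPM (-2.71 ± 0.35, adjusted p = 0.02) and AF357399 from 270 ± 61.2 to 47.0 ± 29.6 (-2.65 ± 0.37, adjusted p = 0.0264). The median log2 difference of all genes was 0.531 here, against 0.368 with median-of-ratios factors, 0.454 with scaling by the total alone and 0.088 for unscaled means. Relative to it, Cd177 stood at 3.04, Lrg1 at 2.74, Retnlg at 1.69, Dfna5 at 1.72, Abhd2 at 1.62, Col1a2 at -3.83, Ttn at -3.08, Mir6236 at -3.24 and AF357399 at -3.18. Over the alternatives and single mice left out the log2 differences ran from -4.58 to -1.26 for Col1a2, -5.45 to -0.64 for Ttn, -3.16 to -2.37 for Mir6236 and -3.12 to -1.50 for AF357399. The weakest values of Col1a2, Ttn and AF357399 came from unscaled means per column, where the pseudocount weighs more. In healthy mice 1 to 4 Col1a2 rested on unscaled signal sums of 27, 9, 27 and 23 and Ttn on 6, 6, 5 and 20.

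Lrg1 lies on chromosome 17 from 56119678 to 56122001, Retnlg on chromosome 16 from 48872621 to 48874496 and Abhd2 on chromosome 7 from 79273199 to 79365508. Col1a2 lies on chromosome 6 from 4504814 to 4541544 and Ttn on chromosome 2 from 76703980 to 76982547. Dfna5 has no entry under that symbol in the annotation used here.

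Within granulocytes, the list of S100 alarmins and granule proteins had a median log2 difference of 1.70 (1.17 above the median of all genes), with 28 of 28 members positive. Cd177 and S100a6, the latter chosen after its value was seen, passed over all genes, and 26 passed when adjusted over the list alone; Ltf stood at 797 and 3955 SPM (3.34 ± 0.92, adjusted p = 0.102) and Lcn2 at 300.2 and 1683 (3.14 ± 0.83, adjusted p = 0.0952). Camera called the list (adjusted p = 3.5e-10; 0.391 with an estimated correlation), and so did fry (adjusted p = 0.040). Of the neutrophil markers, Retnlg, Trem1 and Mxd1 passed over all genes and 18 of 21 adjusted over the list alone, with a median of 2.07 (camera adjusted p = 9.4e-09, 0.292 with an estimated correlation; fry 0.025). Chosen after their values were seen, Trem1, a receptor that amplifies neutrophil activation, rose by 1.53 ± 0.25 and Mxd1, a repressor of the Myc network, by 1.23 ± 0.24 on the log2 scale. The receptors Csf3r and Cxcr2, also chosen later, had log2 differences of 0.63 ± 0.50 (adjusted p = 0.457) and 1.03 ± 0.30 (adjusted p = 0.108). For unscaled means per column, where the pseudocount weighs more, the median of the alarmin and granule list was 1.01 and that of the neutrophil markers 0.93. Healthy mouse 2 overlapped the arthritic mice: S100a8 stood at 52597 SPM in it, at 6184, 9874 and 11530 in healthy mice 1, 3 and 4, and at 26728 to 176598 in the arthritic mice. Of the 5 granulocyte columns of healthy mouse 2, only 2 were not identical to a column of another mouse. Over all classes, the 28 columns it shared with another mouse were all identical to an arthritic column. Part of its value thus comes from columns also found in arthritic mice, but whether these columns raised its S100a8 was not tested. In healthy mouse 4, which stood at 11530 SPM, 12 of 20 granulocyte columns were not identical to a column of another mouse.

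Fry, which asks whether a list's genes move one way, called 4 more lists upward in granulocytes: glycolysis and hypoxia (median 0.80, fry adjusted p = 0.040), toll-like receptor signalling (0.94, 0.031), leukocyte adhesion and migration (0.41, 0.040) and IL-1 and inflammasome (0.75, 0.025). Fry does not take off the median of all genes. Leukocyte adhesion lay 0.13 under it with the scaling used and above it only for unscaled means per column. For those means the medians of glycolysis, toll-like receptor and IL-1 genes were 0.16, 0.16 and 0.14, where that of all genes was 0.088. Camera, which compares a list with other genes, called none of these 4. Camera also called upward nuclear oxidative phosphorylation (adjusted p = 0.029, 0.705 with an estimated correlation, and a median of 0.42, which is 0.11 under the median of all genes with the scaling used and above it only for unscaled means per column). It called 13 lists downward, led by mitochondrially encoded transcripts (median -0.62, adjusted p = 4.1e-09; 0.292 with an estimated correlation) and erythroid transcripts (-1.27, adjusted p = 7.8e-08; 0.425). Markers of B cells (-0.28), T cells (-0.18) and NK cells (-0.28) were among the lists called downward within granulocyte columns, with camera adjusted p of 0.292, 0.481 and 0.301 when the correlation was estimated; none of the 13 was called then (0.292 to 0.571), and fry called none of them. Of the 13, 3 lists, T cell receptor signalling, cytotoxic effector genes and lymphocyte quiescence, had medians of 0.09, 0.08 and 0.01 but means of -0.15, -0.44 and -0.18; T cell markers, B cell receptor signalling and the glucocorticoid response had medians under 0 but means of 0.02, 0.20 and 0.07. Hemoglobin made up 22.3%, 22.4%, 53.7% and 43.2% of the granulocyte signal of healthy mice 1 to 4 and 0.704%, 0.715%, 34.0%, 51.6% and 7.21% of that of arthritic mice 1, 3, 4, 5 and 6.

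Healthy granulocyte signal summed to 59991 to 301431 per mouse and arthritic to 2475988 to 8018851. Of the 46 genes called higher, 13, the matrix metalloproteinase Mmp25 (chosen after its values were seen) among them, were listed at 0 in every healthy mouse, and 22 averaged under 2 SPM there, so their log2 values carry no size. With each mouse thinned to the smallest total, limma called 4 genes, of which 3 were among the 52; without arthritic mouse 1, 3 or 5 it called 0 and without arthritic mouse 4 it called 3. Without healthy mouse 1, 2, 3 or 4 it called 338, 883, 243 and 380, and without arthritic mouse 6, 172. Camera called 10 lists without arthritic mouse 5 and 7 without healthy mouse 3.

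**Figure D3:**
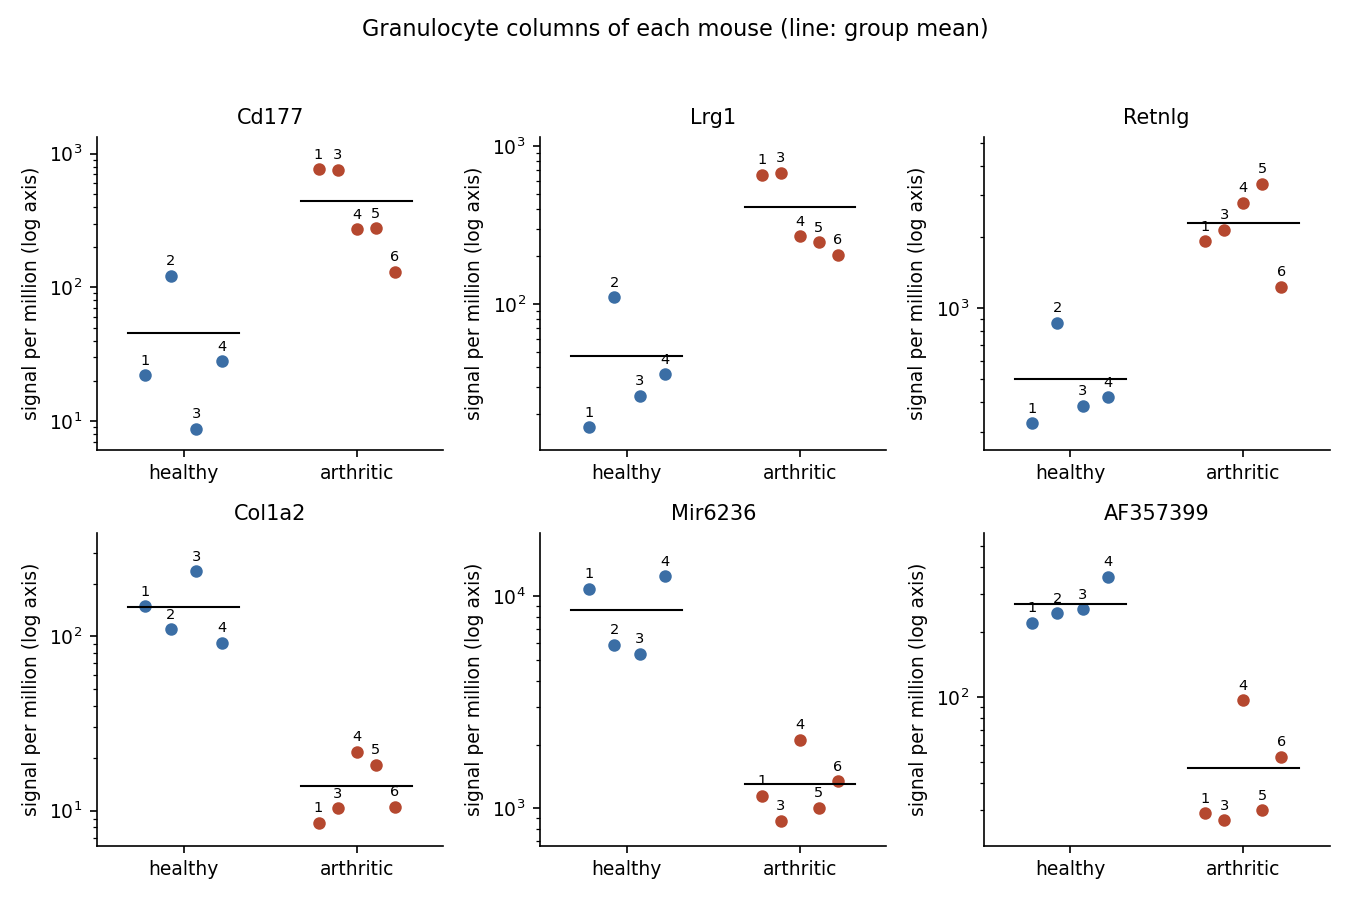
Signal (SPM) (vertical log axis) in the granulocyte columns of each mouse for 6 transcripts; each point is a mouse with its number and the line is the group mean. Col1a2 lay at 91.7 to 237 SPM in healthy mice and at 8.54 to 21.8 in arthritic mice, and healthy mouse 2 gave the highest Cd177 of its group, 122 SPM, from 5 columns.

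The fourth comparison concerned the B-cell class, in healthy mice 1, 2 and 4 and all 5 arthritic mice. The healthy mice held 9, 111 and 15 columns of it, and arthritic mice 1, 3, 4, 5 and 6 held 274, 448, 86, 9 and 348. Of the 15 in healthy mouse 4, 5 were distinct and 3 were not identical to a column of another mouse. Immunoglobulin variable-region genes had the smallest p-values among the genes higher in arthritic mice, but limma called 0 of 9585 genes, with 677 at an unadjusted p under 0.05. Ighv1-85 stood at 0.656 ± 1.14 and 127 ± 121 SPM (SD, n = 3 and 5; log2 difference 5.78 ± 1.00, adjusted p = 0.519) and Igkv6-15 at 4.59 ± 7.95 and 246 ± 150 (6.10 ± 1.153). Ighv3-8, Igkv14-111 and Ighv1-66 had log2 differences of 5.03 ± 0.90, 5.0 ± 0.96 and 5.94 ± 1.25. Each lay higher in 5 of 5 arthritic mice than in every healthy mouse, and each had an adjusted p of 0.519. All 5 were listed at 0 in healthy mice 1 and 4, so their log2 values carry no size. Variable-region genes resemble each other in sequence, so signal can be shared among them. Chosen after their values were seen, the constant region Igkc stood at 3037 SPM in healthy and 25841 in arthritic mice (2.70 ± 0.87) and Jchain, which joins secreted antibodies, at 1408 ± 1107 and 6929 ± 5984 (2.36 ± 1.13), both with adjusted p = 0.519.

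On the low side, the rRNA-annotated CT010467.1 stood at 1309 ± 156 and 749.9 ± 138 SPM (log2 difference -0.82 ± 0.24, adjusted p = 0.519). The kinase Mark3 followed at -1.22 ± 0.37, with Akap8 at -1.07 ± 0.38 and Arhgap4 at -1.59 ± 0.57. The median of all genes was 0.562 in this class. Camera called 6 lists: cytosolic ribosomal proteins (median 0.47, adjusted p = 0.00316) and S100 alarmins (0.65, adjusted p = 0.0467) upward, and erythroid (-1.24, adjusted p = 3.7e-05), mitochondrially encoded (-0.13, adjusted p = 0.0155), lymphocyte quiescence (-0.10, adjusted p = 0.0306) and T cell markers (0.004, adjusted p = 0.0306) downward. With an estimated correlation the adjusted p of all 6 was 1.00, and fry called 0. The ribosomal median lay 0.10 under that of all genes with the scaling used and under it with the other scalings. It lay above only for unscaled means per column, where the pseudocount weighs more, so its direction depended on that setting. Without healthy mouse 2, limma called 59 genes, and without it or without arthritic mouse 5 camera called 2 lists.

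The effect of arthritis was also compared between the granulocyte and B-cell classes of the same mice. Cenpl, a centromere protein, had the smallest p for this difference (log2 difference 5.37 ± 0.65, adjusted p = 0.0738), followed by the zinc-finger gene Hivep1 at 4.28 ± 0.55 and the pseudogene Gm8814 at 4.37 ± 0.56, both with adjusted p = 0.0738. Limma called 0 of 7654 genes for this difference, with 791 at an unadjusted p under 0.05. Cd177 and Mir6236 were therefore not shown to differ in their response between the classes. Without healthy mouse 2 limma called 162 genes and without healthy mouse 4 it called 136.

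Disease stage scores in the labels were 0 in the healthy mice, 1.5 in arthritic mice 1 and 4, 1.5 to 2 in mouse 5, 2 in mouse 3 and 2 to 2.5 in mouse 6. Cd177 over all cells was 325, 161, 276, 213 and 40.9 SPM in arthritic mice 1, 4, 5, 3 and 6, in that order, and Mir6236 was 1551, 2191, 1149, 1318 and 1936. With 5 arthritic mice no correlation with stage was computed.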

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

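Thinning was fixed as an alternative before the data were examined; its bound and the other tests in this part were chosen after results were seen. Of 61 groups of mice examined, 10 held a mouse whose gap to the others took most of the group's range. Chance gives about 1 in 20 such groups.

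Healthy mouse 2 was apart from the other healthy mice in 5 values. It had 201 columns against 26 to 45, a total signal of 2.05397e+06 against 330950 to 560605, 39.3% CD4 T cells against 0 to 6.67% and 2.49% granulocytes against 42.3% to 44.4%. Its 5 granulocyte columns, of which 2 were not identical to a column of another mouse, held 122 SPM of Cd177 against 8.78 to 27.9. Healthy mouse 1 had 13.3% myeloid dendritic cells against 0 to 2.22%.

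Among the arthritic mice, mouse 5 had a median signal per column of 17902 against 8774 to 11266. Its B-cell columns, only 9 in number, held 1219 SPM of Ighv1-66, an immunoglobulin heavy-chain segment, against 26.8 to 244. Mouse 4 had 28.2% of columns in the class named after foxP3 T cells against 1.66% to 5.79%, and 23.4 SPM of Ttn in granulocytes against 5.56 to 7.71. No biological explanation was tested for these single mice.

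Identical columns under different barcodes were the first pattern weighed. Barcode errors would pair near-identical barcodes, but 0.207% of 965 identical pairs within a mouse differed at no more than 1 base. A library deposited under several names would share its barcodes, and 1 of 4309 barcodes occurred in more than 1 mouse. Summing of neighbouring cells before deposit remains a candidate explanation, since 77.6% of distinct columns lay nearer to another column than 2 counting draws of their own values. Of 7316 differences between close columns, only 2 recurred exactly in separate pairs of columns, and no bound had been set for that number. No biological explanation was tested.

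Higher neutrophil granule transcripts, among them Cd177, Ltf and Lcn2, were the second pattern. A larger share of columns deposited as granulocytes does not account for all of it, since the list's median log2 difference was 1.70 within the class and at least 1.58 with any single mouse left out. Columns appear to hold several cells, so this test does not cover fewer granulocytes inside the healthy columns. Over all cells the median was 2.04 as reported, 1.79 with each mouse thinned to the smallest total, 2.36 with the hemoglobin share as a covariate, 1.99 without columns identical to one of another mouse, and 1.14 for unscaled means per column, where the pseudocount weighs more. Signal of other cells in healthy granulocyte columns stays open: granule transcripts differed by 1.78 more than receptor transcripts on the log2 scale (exact permutation p = 0.0952, n = 4 and 5), which cannot be told apart from equal dilution, and S100a8 in granulocytes was low in 3 of 4 healthy mice but not in healthy mouse 2. Only 2 of the 5 granulocyte columns of healthy mouse 2 were not identical to a column of another mouse. Whether the shared columns raised its S100a8 was not tested. Arthritis itself also stays open, as untested.

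Lower signal of Mir6236, Mir6240 and AF357399 was the third pattern. Different shares of the deposited classes do not account for all of it, since the median of the 3 was -2.65 within granulocytes and at most -2.37 with any single mouse left out; in the B-cell class the differences were -1.05 ± 0.43, -0.13 ± 0.74 and -0.19 ± 0.77, none of them called. The median over all cells was -2.20 as reported, -2.35 after thinning and -2.21 with the hemoglobin share as a covariate. More ribosomal RNA in the healthy libraries cannot be told apart from other sources, since the 3 nuclear rRNA genes tested differed by unequal amounts, n-R5-8s1 by -1.17 ± 0.21, CT010467.1 by -0.59 ± 0.22 (the median) and Gm24601 by -0.34 ± 0.39. Gm42418, whose interval lies within that of CT010467.1, went the same way, at 5.37% of the signal of healthy and 1.80% of that of arthritic mice. Its lowest healthy share, 3.34%, lay above its highest arthritic share, 2.68%. Arthritis, signal of other cells in healthy granulocyte columns (Mir6236 and AF357399 were among the leading genes of the CD4 T class) and any difference in handling between the groups, which the labels do not describe, stay open.

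Splits of the mice were compared, the real one counted among them, with the scaling used only. Over all cells and in granulocytes 100 of 126 possible splits were run. Over all cells 3 of 100 splits gave at least the 4 genes called, a share under 5%, but 6 of 100 gave at least its 1133 genes at an unadjusted p under 0.05 (highest other 1829), so chance is not firmly excluded, and the highest other split called 175. That split set healthy mice 3 and 4 and arthritic mice 4 and 5, the 4 with the highest hemoglobin shares, against the rest, which points to a structure of the samples along hemoglobin. In granulocytes 1 of 100 splits, the real one, gave as many as 52 genes, the highest other giving 22, so chance is unlikely for independent mice and this scaling. The real split called 5 genes with median-of-ratios factors and 4 after thinning, where no other splits were run. It also divides the mice by granulocyte signal, 59991 to 301431 against 2475988 to 8018851, so the splits cannot tell arthritis from depth. The mice were not independent, since 11.6% to 20.1% of the columns of each arthritic mouse were identical to one of another mouse and at most 3.88% to one of a healthy mouse, so an effect of values shared within the group stays open. In B cells and for the difference between classes the real split called 0 genes, so all 56 splits give as many and nothing follows from it; the highest others gave 128 and 0. For gene lists, chance cannot be excluded: 12 of 100 splits gave as many as 17 over all cells (highest other 21), 10 of 100 as many as 16 in granulocytes (highest other 20) and 22 of 56 as many as 6 in B cells (highest other 10).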

How the results depend on the processing

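Chosen only after results were seen were pseudocount 5, array weights, signal by the total alone, the hemoglobin covariate, the settings on identical columns and on barcodes ending in N, leaving out the 2 arthritic mice of lowest hemoglobin share, unscaled means, mice with shared numbers without the block, and the exact test of lists. So was the removal of genes in classes.

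Of 2161 values of 139 named genes under these settings and those fixed earlier, 2034 kept their direction and side of the threshold, 71 lost and 29 gained a call, and 27 reversed. With single mice left out the numbers were 1152, 62, 15 and 3 of 1232. Most of the 139 were not called in the first place, so a call could be lost only among the few that were. Over all cells Cd177 stayed called in 1 of 9 fits with a single mouse left out, and Mir6236 in 4. In granulocytes Col1a2 stayed called in 6 of 9 such fits. None of the called genes reversed. Mir6236 in granulocytes was called under 19 of 25 alternatives and Col1a2 under 20, against 9 for Ttn; over all cells Cd177 was called under 11 and Mir6236 under 15.

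Over all cells, 4 genes were called. The number was 19 with scaling by the total alone (1 of the 4 among them), 0 with no filter on low values, 7 with pseudocount 5, 0 with array weights, 7 without hemoglobin, platelet-marker and ribosomal protein genes, 28 with median signal and 37 with hemoglobin share as a covariate. It was 0 without the 2 arthritic mice of lowest hemoglobin share, 31 for unscaled means, 40 with mouse number as a block and 29 for those mice without the block. Leaving out single mice gave 0 to 64, the latter without arthritic mouse 6. Mice of 1 number were not alike here (correlations of -0.17 to 0.11), so the block removed mice rather than a shared effect.

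In granulocytes, 52 genes were called. The number was 5 with median-of-ratios factors, 2 with scaling by the total alone, 2801 with no filter, 175 with pseudocount 5, 283 with array weights and 291 without hemoglobin, platelet-marker and ribosomal protein genes. It was 1 with median signal and 9 with hemoglobin share as a covariate (8 of them among the 52), 4 after thinning, 457 without columns identical to one of another mouse and 746 without barcodes ending in N, both with 3 healthy mice. It was 0 without the 2 arthritic mice of lowest hemoglobin share, 190 with the block (22 of the 52 among them) and 211 for those mice without it (35). Leaving out single mice gave 0 (without arthritic mouse 1, 3 or 5) to 883 (without healthy mouse 2). In B cells 0 became 13 with the block but stayed 0 for those mice without it, so the block itself made these calls, and 0 to 59 with single mice left out, 59 without healthy mouse 2. For the difference between classes single mice gave 0 to 162, the latter without healthy mouse 2. Beyond fewer mice or genes, the cause was not tested.

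For gene lists over all cells, 17 became 0 with an estimated correlation, 0 with fry and 0 with exact permutation, and 13 to 18 with single mice left out. In granulocytes 16 became 0, 6 and 0, and 7 to 18. In B cells 6 became 0, 0 and 0, 2 with the block, and 2 to 7. The exact test can call a list after adjustment only where many lists reach its smallest p, 0.0159, or 0.0357 in B cells.

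For cell class shares (B cells), the difference of -4.46 points became 1.07 with each distinct column once, 1.99 without identical columns and 5.97 with the block, and ran from -13.4 to 3.75 with single mice left out, 3.75 without healthy mouse 2. For cell class shares (CD4 T cells) it became 0.15 on the logit scale and 6.89 with the block, and ran from -7.08 to 6.02, the latter without healthy mouse 2. For granulocytes 16.7 became 0.32 with the block. For dendritic cells it ran from -2.54 to 1.90, the latter without healthy mouse 1.

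Reversed log2 differences without columns identical to one of another mouse were 0.23 for Arhgap4 in B cells and, over all cells, 0.66 for Ifi47, 0.060 for H2-Aa, 0.13 for H2-DMb2, 0.089 for H2-T22, 0.14 for H2-Q6, 0.068 for Nfatc3, 0.23 for Plcg1, 0.075 for Gzma, 0.41 for Ikzf2, 0.54 for Tnfrsf4 and 1.397 for Fcer2a (all cells). With the hemoglobin covariate Hba-a2 stood at 0.030, Alas2 at 0.20, Hbb-bs at 0.20 and Pf4 at 0.62. Without the 2 arthritic mice of lowest hemoglobin share they stood at 0.36, 0.26, 0.31 and 0.48, and Pf4 at 0.48 after thinning. With the block, and for those mice without it, Tyrobp stood at -0.032, Ear2 at -0.22 and Thbs1 at -0.16. With single mice left out Gzma ran from -0.88 to 0.0094 and Pf4 from -0.94 to 0.42. In granulocytes depth was lower in the healthy mice, with 59991 to 301431 signal per mouse against 2475988 to 8018851. In the B-cell class the lowest signal was that of an arthritic mouse, 98052 against a healthy lowest of 115716.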

Other observations

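All values in this part were chosen after they were seen, and no explanation was tested for them. In granulocyte columns, some transcripts of connective tissue and muscle were higher in healthy mice, which held 5 to 20 such columns each. No list of such genes was tested. Myh4, a muscle myosin, stood at 37.9 ± 4.17 SPM in healthy and 4.90 ± 3.42 in arthritic mice (SD, n = 4 and 5; log2 difference -2.87 ± 0.52, limma adjusted p = 0.0342). Col1a1 had a log2 difference of -1.60 ± 0.71 (adjusted p = 0.223) and the muscle troponin Tnnt3 one of -2.02 ± 0.54 (adjusted p = 0.0968), in the same direction as Col1a2 and Ttn. The actins Actc1 and Acta2 went the other way, by 1.32 ± 0.61 and 0.90 ± 0.46 (adjusted p = 0.233 and 0.270).

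Antibody transcripts in the B-cell class varied widely among arthritic mice, of which mouse 5 held only 9 columns of the class. Igkc stood at 34527, 18620, 16398, 57455 and 2207 SPM in arthritic mice 1, 3, 4, 5 and 6, and at 1213, 5125 and 2774 in healthy mice 1, 2 and 4. Ighg1, the constant region of an IgG subclass, stood at 9762, 4484, 97.9, 18264 and 102 SPM in the same arthritic mice.

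The rare classes held few columns. The mast cell class had 5 columns, all from arthritic mice and 4 of them identical, with Mcpt8 at 61031 and Prss34 at 22584 SPM, both proteases of basophils and mast cells. The macrophage class had 2 columns, identical to each other, with Lyz2 at 82537 and C1qb at 5986 SPM. The osteoblast class had 1 column, with Col1a2 at 18741 and Col1a1 at 12469 SPM. In the common myeloid progenitor class, Mpo stood at 1031, Elane at 1144 and the carbonic anhydrase Car2 at 5732 SPM.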
